A study of Mus musculus with 6 samples.

How the data were processed

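RNA sequencing read counts were analysed for CD4+ T cells isolated from a splenic single-cell suspension of C57BL/6 mice at the acute phase of experimental autoimmune encephalomyelitis. There were 6 libraries, 3 from mice labelled Ogt-KD (genotype Ogtfl/wt CD4-Cre) and 3 from control mice with the wild-type genotype. Cells were flash frozen, RNA was taken up in Trizol, and libraries were made with an Illumina TruSeq kit. The authors' processing notes name Bowtie2 2.0.6, TopHat2 2.0.9 and the mouse build mm9. The tool that counted reads, its strand setting and the test behind the authors' comparison are not given in the sources used here.

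The deposited table holds integer read counts per Ensembl gene for each library, in counts. It also holds the authors' FPKM, which the values show to be the count over the gene length in kilobases and over 1 constant per library. The authors' mean normalised signal per group was read for description only. The authors' log2 fold change of Ogt-KD over control, with the authors' p value and adjusted p, was compared with the tests run here. The deposited gene length is in bases, an other unit that entered this check of the FPKM and nothing else. The check of length bias took the length of each gene's longest GENCODE M21 transcript. Of the 54532 gene identifiers, 54409 matched GENCODE release M21 (GRCm38), 53499 of them with identical coordinates, and all 54409 overlapped. The coordinates in the table are therefore those of GRCm38 and not of mm9, and positions below are on GRCm38.

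Total counts were 22768353, 24917282 and 18127031 in control replicates 1, 2 and 3, and 19563894, 18969803 and 25683453 in Ogt-KD replicates 1, 2 and 3. Intervals on counts cover counting error only, since they pool the libraries of each group and leave out the spread between mice. The reads carry no molecular identifiers, so repeated reads of 1 molecule could not be merged. A check for repeated libraries compared every pair over genes with a summed count of at least 20. The chi-squared per degree of freedom ran from 10.8 to 96.2 and Spearman's correlation across genes from 0.970 to 0.991, so no pair was a copy of another. Across genes, observations are not independent replicates.

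The main comparison used the edgeR 4.0.16 quasi-likelihood F test with robust dispersion, TMM normalisation and filterByExpr, in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 28456 genes with a count in any library, 16075 passed the filter. Normalised read counts are given as CPM, the count unit of edgeR scaled by library size and TMM factor, with the SD over n = 3 libraries, and log2 fold changes of Ogt-KD over control with their SE. The main test, its samples, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined.

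The labels state no pairing of mice. After each group's mean was removed, the deviations of control and Ogt-KD libraries with the same replicate number correlated across genes at 0.109, 0.347 and 0.523, all above 0.1. Of the 6 pairs with different numbers, control replicate 2 and Ogt-KD replicate 1 had 0.267, above the 0.109 of the first pair, control replicate 1 and Ogt-KD replicate 2 had 0.0736, and 4 lay between -0.418 and -0.122. Replicates 1 and 2 are thus not clearly told apart as pairs. The pairing by replicate number comes from the data's deviations under shared numbers. The same counts are then tested with it, so the p values of such a fit can be too small. An edgeR fit with the replicate number as an additive term (the replicate block) was run beside the main comparison. Its values are printed where it changes a call or moves a count of calls by more than 1.5 times.

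Gene lists covered helper T cell programmes, signalling, metabolism, ribosomes, histones and the markers of other cell types that a spleen suspension could hold. Each list with at least 3 tested members was tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, which compares the list with all other genes and decided the call. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move on balance in 1 direction, and its mixed test whether they change in either direction, and neither compares the list with other genes. P values were adjusted over 35 lists for each test. Members passing were counted over all genes tested and adjusted over the list alone.

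Named genes were Ogt and Mgea5 (the gene for O-GlcNAcase), lineage genes, Xist and Ddx3y, and up to 4 members of each list with the smallest p. When fewer than 10 genes passed, the rule took the 10 with the smallest p in each direction, and these did not pass. It kept those whose 3 Ogt-KD values all lay on one side of the control values, at an average log2 CPM of at least 1 and with a symbol that was not a clone, predicted gene or receptor segment. Gm33707, Gm38326, H2-Ab1, H2-Eb1, Cd74, Cd4, Eno1, Prf1, Zbtb46, Slc4a1, Hsph1, Plxnb2, Msr1, Ccr3, Tgif1-ps, Try4 and Ctrb1 fell outside the rule and were chosen after their values were seen. Some genes taken by the rule are not reported here.

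Immunoglobulin and T cell receptor segments were summed as CPM per library and compared by a two-sided exact permutation test, and also within pairs of equal replicate number over sign flips, a test added after the data were seen. Genes within 5 Mb of Ogt were compared with 10000 random lists matched on mean expression. Alternatives were other scalings, no filter, a mean CPM of at least 5, non-robust dispersion, DESeq2 1.42.0, limma-voom, limma on log2 FPKM, each library left out in turn, and immunoglobulin, haemoglobin and mitochondrial genes left out. Both replicate 3 libraries left out, DESeq2 with the replicate block, the block without each pair, and a GC content and length correction were added after the data were seen.

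The tests were checked on data simulated from these libraries, with 200 changed genes in each of 5 simulations. Without a block edgeR recovered 8.4% of genes changed 1.5-fold, 44% of those changed 2-fold, 78.8% at 4-fold and 96.4% at 8-fold, and 7.78% of its calls were false. With the replicate block it recovered 42.4%, 64%, 93.6% and 98.8%, and 14.3% of its calls were false, above the nominal 5%. The blocked fit ran on data simulated with differences between the pairs built in and with its own dispersions. Its shares thus assume that replicate numbers are pairs, and both fits were not compared on the same simulated data. In 1 simulation 30.1% of the calls of DESeq2 were false, against 7.69% for limma-voom. The reads themselves were not realigned, and exon-level or splice-level values were not analysed here.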

Results

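CD4+ T cells were taken from the spleens of mice with experimental autoimmune encephalomyelitis (EAE), an induced autoimmune disease of the central nervous system, at its acute phase. Their RNA was sequenced in 3 mice labelled Ogt-KD and 3 control mice. Ogt, on the X chromosome, encodes O-GlcNAc transferase, the enzyme that attaches N-acetylglucosamine to serine and threonine residues of nuclear and cytoplasmic proteins. The Ogt-KD mice carried 1 floxed and 1 wild-type allele of Ogt with a Cre recombinase driven by Cd4 regulatory sequence, which is active in T cells. Total counts ran from 18127031 to 25683453 per library. The control mice are labelled wild type, with no Cre or floxed allele named. The comparison asks which genes the CD4+ T cells of the Ogt-KD mice expressed differently during the disease. An effect of the Cre, or of DNA linked to it or to the floxed allele, cannot be told apart from an effect of Ogt.

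Ogt RNA did not differ between the groups by more than the replicate spread. Ogt (X:101640060-101684351 on GRCm38) stood at 597 ± 32.8 CPM in control and 573 ± 104 CPM in Ogt-KD libraries (SD, n = 3 each), a log2 fold change of -0.06 (SE 0.15, 95% interval -0.41 to 0.30, edgeR adjusted p = 0.981). The Ogt-KD libraries held 661.9, 598.8 and 458.6 CPM and the control libraries 599.2, 627.9 and 562.4 CPM in replicates 1, 2 and 3. Without Ogt-KD replicate 3 the log2 fold change was 0.08. These counts are per gene and include exons that a floxed deletion may leave in place, so they do not measure the deletion. As bulk values they also do not show whether Ogt was lowered evenly or in a part of the cells only. Mgea5, which encodes the enzyme that removes O-GlcNAc, stood at 240 and 228 CPM (log2 fold change -0.08, SE 0.10). Of 14 tested genes of hexosamine synthesis and O-GlcNAc cycling, 7 lay above and 7 below 0 and none passed when adjusted over the list alone or over all genes (median -0.01, mean 0.03, camera direction up, adjusted p = 0.749). Gfpt1, the entry enzyme of the hexosamine pathway, had a log2 fold change of 0.15 (SE 0.16). Ddx3y, on the Y chromosome, had 0 counts in every library, which allows up to 3 counts in each, and Xist stood at 1003 ± 48.0 and 1264 ± 273 CPM (SD, n = 3 each).

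The gene with by far the smallest p value was Gm33707, a processed pseudogene on chromosome 3 (60769887-60770455), which rose in the Ogt-KD libraries with 1008, 782 and 851 reads against 0, 0 and 1 in the controls. The ratio of normalised counts was 2613, with a 95% counting interval from 468.6 to 103300 (edgeR adjusted p = 0.000554). It was the 1 gene of 16075 past the threshold in edgeR without a block, where 1209 genes had an unadjusted p under 0.05 (810 higher and 399 lower) and 804 would by chance. That excess depends on the libraries kept. Genes at an unadjusted p under 0.05 numbered 737 of 16339 without control replicate 1 and 784 of 16682 without Ogt-KD replicate 1. They numbered 719 of 16648 without Ogt-KD replicate 2, and each of these shares is under 5%. The number was 1083 of 16328 without control replicate 2 and 990 of 16732 without control replicate 3. It was 3000 of 16329 without Ogt-KD replicate 3. Leaving out a library also leaves fewer samples for the test. The neighbouring long noncoding RNA gene Gm38326, 17.9 kb away, had 47, 42 and 36 reads against 0, 0 and 1, a ratio of 124 (interval 21.8 to 4924, adjusted p = 0.117 with edgeR, 0.0363 with the replicate block). DESeq2 called 111 genes, edgeR without a filter 4 and limma-voom 1. The count was 2 without Ogt-KD replicate 2 and 2 without Ogt-KD replicate 3. Groups did not overlap for 2140 genes, 13.3% of those tested, where chance gives 10%.

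With the replicate number as a block, edgeR called 47 genes, 32 higher and 15 lower in Ogt-KD libraries, with 2119 at an unadjusted p under 0.05. The labels state no pairing, so these calls rest on a pairing read from the same counts. Their p values can thus be too small. Il18rap, a chain of the interleukin 18 receptor, stood at 43.4 ± 2.91 CPM in control and 77.5 ± 3.32 CPM in Ogt-KD libraries (log2 fold change 0.84, SE 0.09, edgeR adjusted p = 0.117, 0.0363 with the block). Other genes higher with the block were Socs2 (0.87), Tnfrsf4 (0.76), which encodes the costimulatory receptor OX40, Il10ra (0.74), Cish (0.64) and Nrn1 (1.19, a gene that overlaps Fars2 on the other strand). Ampd1, an AMP deaminase (-1.22), and the Hsp90 co-chaperone Fkbp4 (-0.67) were lower with it. In edgeR none of these genes passed without the block, at adjusted p values of 0.117 for Il18rap and 0.48 for Socs2, Tnfrsf4, Il10ra, Nrn1, Ampd1 and Fkbp4. Cish had an edgeR adjusted p of 0.537 without it. In the authors' table all of these genes except Cish had an adjusted p under 0.05. The authors' values ran from 1.14e-06 for Il18rap to 0.00471 for Il10ra. They come from the same 6 libraries and are not independent evidence for the calls with the block. Within the blocked fit the count rests on the pairs: it was 295 without replicate 1 of both groups, 2 without replicate 2 and 295 without replicate 3. With both replicate 3 libraries left out and no block it was 35, of which 5 were among the 47.

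The other genes with the smallest p values passed in neither edgeR fit. On the higher side these were C1qtnf6 (log2 fold change 1.15), Il18r1 (0.62), the partner chain of the interleukin 18 receptor, Ttc39c (0.67), Glrx (0.63) and Pcyt1b (1.35). On the lower side they were Vmn2r97 (-0.49), a member of a large family of similar receptor genes, Crim1 (-0.43), Col11a2 (-0.69), Arhgef11 (-0.48), Klf2 (-0.49), Dnajb4 (-0.76), Celsr2 (-0.72) and Abcc5 (-0.38). Their adjusted p values in edgeR were 0.48 without the block and ran from 0.0517 for Glrx to 0.0952 for Abcc5 with it.

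**Figure D1:**
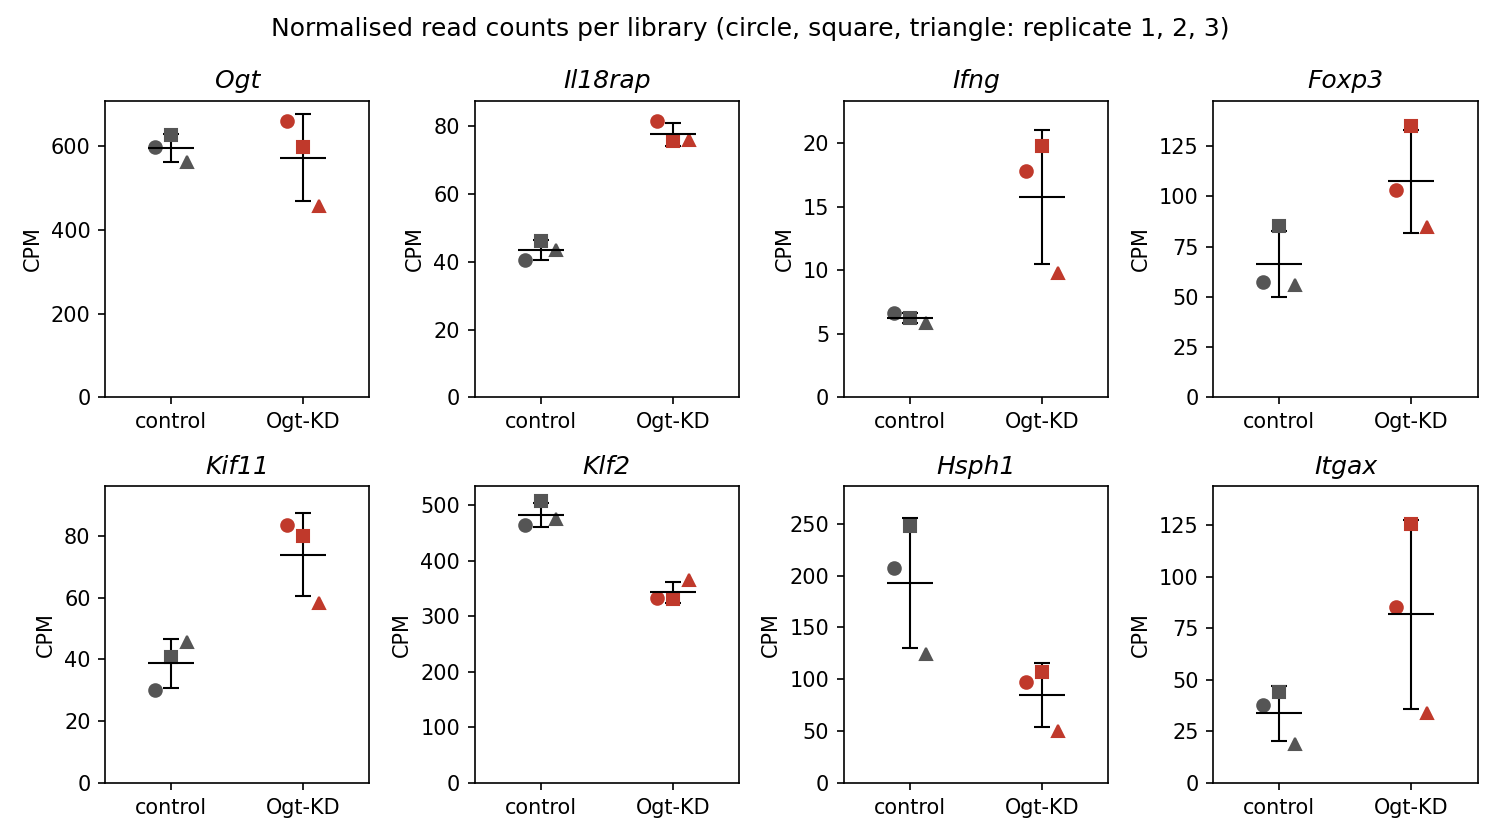
Normalised read counts (CPM, vertical axes from 0) of Ogt, Il18rap, Ifng, Foxp3, Kif11, Klf2, Hsph1 and Itgax in each of 3 control and 3 Ogt-KD libraries, with the mean and SD as bars and circle, square and triangle for replicates 1, 2 and 3. The Ogt means are 597 and 573 CPM, and those of Il18rap 43.4 and 77.5 CPM.

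Genes of the Th1 programme, the helper T cell state that makes interferon gamma, were higher as a group in Ogt-KD libraries. Of 18 tested members 16 lay above 0, the median log2 fold change was 0.74, and 11 rose when adjusted over the list alone, while 0 passed over all genes (camera adjusted p = 1.99e-20, and adjusted p = 0.1001 with an estimated correlation). With the replicate block 14 rose adjusted over the list alone and 3 over all genes, among them Il18rap and Ccl5. Ifng, the signature cytokine, stood at 6.25 ± 0.383 and 15.8 ± 5.31 CPM (log2 fold change 1.33, SE 0.27, n = 3 each). Cxcr3 had a log2 fold change of 0.48 (SE 0.12) and Ccl5 of 1.04 (SE 0.28). Tbx21, which encodes the Th1 master regulator T-bet, stood at 17.1 ± 4.38 and 29.9 ± 12.5 CPM (0.80, SE 0.36) and did not pass adjusted over the list alone without the block. Dendritic cell and antigen presentation markers were higher in the same libraries with a median of 0.86, and erythroid markers with a median of 1.45. Replicate 3 of both groups lay apart from Ogt-KD replicates 1 and 2 on the first principal component, which held 44.8% of the variance. Without both replicate 3 libraries the Th1 median was 0.80.

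Genes of the regulatory T cell programme were higher too, with a median log2 fold change of 0.50. Of 21 tested members 19 lay above 0 and 10 rose adjusted over the list alone, 0 over all genes (camera adjusted p = 8.41e-16, and adjusted p = 0.260 with an estimated correlation). With the block 13 rose adjusted over the list alone and 4 over all genes, Foxp3, Ikzf2, Tnfrsf4 and Socs2. Foxp3, the regulatory T cell transcription factor, stood at 66.2 ± 16.4 and 107 ± 25.5 CPM (0.70, SE 0.22, edgeR adjusted p = 0.583, 0.0427 with the block), and its locus overlaps the noncoding gene Flicr on the same strand. Ikzf2, which encodes Helios, had a log2 fold change of 0.69 (SE 0.15, edgeR adjusted p = 0.483, 0.0406 with the block). The costimulatory receptor genes Tnfrsf4 and Tnfrsf18 had 0.76 and 0.50, and the interleukin 2 receptor chain Il2rb 0.52. Tnfrsf4, Tnfrsf18 and Il2rb are also made by activated conventional T cells. The activation list was higher with these genes, with a median of 0.27, and so were the dendritic cell markers at 0.86.

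Th2 genes were higher by a smaller amount. Of 8 tested members 6 lay above 0, with a median log2 fold change of 0.26 (camera adjusted p = 0.0196, and adjusted p = 0.317 with an estimated correlation). Adjusted over the list alone 2 rose, Il1rl1 (1.14), which encodes the interleukin 33 receptor ST2, and the chemokine receptor gene Ccr8 (1.22). Both genes are also expressed by regulatory T cells, and 0 members passed over all genes without the block, against these 2 with it. Gata3 (0.22, SE 0.19) and Il4 (0.12, SE 0.36) did not pass. The call was lost without control replicate 1 (adjusted p = 0.0550 by camera), without control replicate 3 (0.188) and without Ogt-KD replicate 2 (0.109). It was also lost without a filter (0.121) and without both replicate 3 libraries (0.0710). The median of the list was 0.43 without control replicate 2, 0.11 without control replicate 3 and 0.09 without Ogt-KD replicate 2.

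The Th17 and follicular helper lists did not pass. The 17 tested Th17 genes had a median log2 fold change of 0.07 (camera adjusted p = 0.289), with Il17a at -0.26 (SE 0.85). Il17a stood at 1.54 ± 1.23 and 1.28 ± 1.39 CPM (SD, n = 3 each), a level too low for a precise fold. The 12 follicular helper genes had a median of 0.13 (camera adjusted p = 0.270), and Bcl6, their lineage regulator, had -0.03 (SE 0.13). No member of either list passed adjusted over the list alone without the block, and with it 3 Th17 genes rose and 1 fell. Camera called the Th17 list higher without control replicate 2 (adjusted p = 0.0191), and its direction was down without control replicate 1 and without Ogt-KD replicate 3 (0.894 and 0.834). It called the follicular helper list higher without control replicate 3 (0.0207) and without Ogt-KD replicate 2 (0.00968), with a direction of down without control replicate 1 and without Ogt-KD replicate 3 (0.691 and 0.730).

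Cell cycle genes were higher in Ogt-KD libraries, with 37 of 38 tested members above 0 and a median log2 fold change of 0.76. Adjusted over the list alone 24 rose and 0 over all genes (camera adjusted p = 4.09e-30, and adjusted p = 0.265 with an estimated correlation), against 15 with the block adjusted over the list alone. Kif11, a mitotic spindle motor, stood at 38.8 ± 7.90 and 74.0 ± 13.6 CPM (0.93, SE 0.19), Cenpf had 0.88, Nusap1 0.79 and Top2a 0.77, each of them among the 24. The erythroid list was higher as well, at a median of 1.45, and erythroid precursors also divide. Among the Ogt-KD libraries replicate 3 had the highest erythroid score (0.99) and the lowest cell cycle score (-0.10). Without it the cell cycle median was 0.87 and the erythroid median 0.72. The cell cycle scores of control and Ogt-KD libraries were -0.74 and 0.57 in replicate 1, -0.13 and 0.50 in replicate 2, and -0.15 and -0.10 in replicate 3. The median was 0.56 without control replicate 1 and 0.40 with the block without replicate 1 of both groups, where camera still called the list (adjusted p = 6.68e-14).

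Naive and quiescence genes were lower in Ogt-KD libraries, with 19 of 20 tested members below 0 and a median log2 fold change of -0.25. Adjusted over the list alone 1 gene fell, Klf2, a transcription factor of quiescence and lymph node homing, at 483 ± 21.8 and 343 ± 19.3 CPM (SD, n = 3 each). The camera adjusted p was 2.01e-08, and the adjusted p was 0.265 with an estimated correlation. Tgfbr2 (-0.36), Treml2 (-0.61) and Satb1 (-0.36) had the next smallest p values, and 8 members fell with the block adjusted over the list alone, of which 1, Treml2, passed over all genes. Activation and checkpoint genes were higher, with 14 of 20 above 0, a median of 0.27 and 4 that rose adjusted over the list alone (camera adjusted p = 7.32e-06, and adjusted p = 0.260 with an estimated correlation). These 4 were Tnfrsf4 (0.76), Tnfrsf9 (0.78), Tnfrsf18 (0.50) and Gzmb (1.32), which encodes granzyme B. With the block 9 rose and 1 fell adjusted over the list alone, and 1, Tnfrsf4, passed over all genes. Without Ogt-KD replicate 3 the median of the activation list was 0.14. Dendritic cell markers were higher in the same libraries at a median of 0.86.

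Migration genes and chemokine receptors had a median log2 fold change of 0.15 over 25 tested members. Adjusted over the list alone 3 rose, among them Cxcr3 and Ccr8, and Cxcr4 (-0.999), the receptor for Cxcl12, fell (camera adjusted p = 0.00769, and adjusted p = 0.260 with an estimated correlation). With the block 7 rose and 2 fell adjusted over the list alone, and 2 passed over all genes. The call was lost without control replicate 3 (camera adjusted p = 0.0592) and without both replicate 3 libraries (0.122). Its median was 0.08 without control replicate 1, 0.08 without control replicate 2, and 0.07 without Ogt-KD replicate 1 and also without Ogt-KD replicate 3. Immediate early genes, which respond to stimulation and to tissue dissociation, had a median of -0.12 over 30 members with 18 below 0 (camera adjusted p = 0.00520, and adjusted p = 0.670 with an estimated correlation). None passed adjusted over the list alone without the block. With it 9 fell and 2 rose adjusted over the list alone, and 1, Tnfaip3 (-0.81), an inhibitor of NF-kB signalling, passed over all genes. Klf6 had -0.49, Fos -0.89 and Jund -0.35. The call was lost without control replicate 2 (0.282, list median -0.0002) and without Ogt-KD replicate 3 (0.447), as it was without both replicate 3 libraries (0.111).

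Ribosomal protein genes were lower by a small amount, with 43 of 44 tested members below 0 and a median log2 fold change of -0.17, and 0 passed adjusted over the list alone (camera adjusted p = 0.000163, and adjusted p = 0.674 with an estimated correlation). Scores of control and Ogt-KD libraries were 0.23 and -0.28 in replicate 1, -0.18 and -0.42 in replicate 2, and 0.23 and 0.42 in replicate 3, the opposite direction in the pair that lies apart on the first principal component. The call was lost without Ogt-KD replicate 2 (camera adjusted p = 0.330, median -0.02) and with the block without replicate 1 of both groups (0.388, median -0.01). The median was -0.08 without control replicate 1, -0.31 without control replicate 2, -0.07 without Ogt-KD replicate 1 and -0.46 without Ogt-KD replicate 3. The mitochondrially encoded genes had a median of -0.13 over 15 members and passed camera with the block (adjusted p = 0.0215) but not without it (0.0702), with an adjusted p of 0.635 and 0.711 at an estimated correlation. Without the block camera called them lower without control replicate 2 (0.000307, median -0.28) and without Ogt-KD replicate 3 (1.57e-05, median -0.44), and the median was 0.01 without Ogt-KD replicate 2. It was -0.03 without control replicate 1, -0.04 without control replicate 3 and -0.06 without Ogt-KD replicate 1.

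The remaining lists of signalling and metabolism did not pass camera without or with the block on all 6 libraries, and several passed when 1 library was left out. Median log2 fold changes were -0.04 over 30 T cell receptor signalling genes (adjusted p = 0.0800), 0.07 over 30 JAK STAT genes (0.131) and 0.04 over 26 NF-kB genes (0.395). They were -0.02 over 38 type I interferon response genes (0.399), 0.01 over 28 apoptosis genes (0.395) and 0.09 over 23 glycolysis genes (0.222). Oxidative phosphorylation had -0.0032 over 42 genes (0.660), cholesterol and fatty acid synthesis -0.04 over 27 (0.0682) and the unfolded protein and stress response -0.09 over 24 (0.0905). Ribosome biogenesis had -0.07 over 24 (0.0973), RNA splicing factors -0.05 over 32 (0.195) and histone genes 0.26 over 17 (0.140). With single libraries left out the medians ran from -0.11 to -0.02 for T cell receptor signalling, -0.04 to 0.17 for JAK STAT, -0.01 to 0.07 for apoptosis, 0.05 to 0.10 for glycolysis, -0.12 to -0.04 for the stress response, -0.07 to -0.04 for ribosome biogenesis, -0.08 to -0.03 for splicing factors and 0.12 to 0.35 for histone genes. Within the JAK STAT list 3 genes rose adjusted over the list alone, Socs2, Il10ra and Il2rb, and with the block 3 passed over all genes, Socs2, Il10ra and Cish. The block also brought 3 apoptosis genes up, 1 NF-kB gene down, and 1 up and 1 down in both the interferon and the stress response list when adjusted over the list alone, from 0 without it. Camera called the T cell receptor signalling list lower without control replicate 3 (adjusted p = 0.00778) and without Ogt-KD replicate 1 (0.0140). It called the JAK STAT list higher without control replicate 2 (0.0191) and without Ogt-KD replicate 3 (0.0421). Interferon genes were called in both directions, higher without control replicate 2 (0.0181) and without Ogt-KD replicate 3 (0.0421), and lower without control replicate 3 (0.00125) and without Ogt-KD replicate 2 (9.68e-11). Oxidative phosphorylation was called lower without control replicate 2 (0.0225) and without Ogt-KD replicate 3 (0.00356). Cholesterol synthesis was called lower without control replicate 3 (0.0348), without Ogt-KD replicate 1 (0.00103) and without Ogt-KD replicate 2 (0.00494), and the stress response without control replicate 1 (0.0469). Without a filter camera called T cell receptor signalling (0.0291), cholesterol synthesis (0.0230) and ribosome biogenesis (0.0458) lower.

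Markers of other cell types differed between the groups as well. Dendritic cell and antigen presentation genes had 20 of 20 tested members above 0 and a median log2 fold change of 0.86, with 7 at an unadjusted p under 0.05 and 0 passing adjusted over the list alone (camera adjusted p = 4.17e-12, and adjusted p = 0.317 with an estimated correlation). With the block 15 rose adjusted over the list alone and 4 over all genes, among them Itgax, which encodes CD11c (1.27, SE 0.49), Zbtb46 (1.43), a transcription factor of conventional dendritic cells, and the MHC class II genes H2-Ab1 (1.04) and H2-Eb1 (1.07). H2-Ab1 stood at 203 ± 79.96 and 419 ± 202 CPM (SD, n = 3 each). H2-Oa had 0.91 and H2-Ob 0.35. The dendritic cell median was 0.58 without control replicate 3 and 0.52 without Ogt-KD replicate 2. Erythroid genes had 18 of 20 above 0 and a median of 1.45, and 9 rose adjusted over the list alone, with 0 over all genes (camera adjusted p = 1.06e-16, and adjusted p = 0.260 with an estimated correlation). Car2 had 1.49, Rhag 2.82 and Hemgn 2.22, and Slc4a1 (2.92) and Car2 were among those that passed over all genes with the block. The erythroid median was 0.72 without Ogt-KD replicate 3.

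Macrophage and monocyte markers were lower, with 19 of 24 tested members below 0 and a median log2 fold change of -0.48 (camera adjusted p = 0.0177, and adjusted p = 0.670 with an estimated correlation). None passed adjusted over the list alone without the block, and with it 14 fell and 1 rose. Fcgr1, an IgG receptor of macrophages, had -1.02 (SE 0.40), and the lysozyme gene Lyz1 had 1.55 (SE 0.35), the opposite direction. The macrophage call was lost without control replicate 3 (adjusted p = 0.749 by camera, median 0.05), without Ogt-KD replicate 1 (0.346, median -0.13) and without Ogt-KD replicate 2 (0.246, median -0.16), and the median was -1.44 without Ogt-KD replicate 3. Neutrophil markers were higher, with 20 of 22 above 0, a median of 0.42 and 0 passing adjusted over the list alone (camera adjusted p = 0.00584, and adjusted p = 0.670 with an estimated correlation). That call was lost without control replicate 1 (0.274, median 0.20) and without Ogt-KD replicate 2 (0.967, median -0.03). With the block 1 neutrophil gene rose adjusted over the list alone. The neutrophil median was 0.67 without control replicate 3, 0.70 without Ogt-KD replicate 1 and 0.68 without Ogt-KD replicate 3.

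NK and cytotoxic genes were higher, with 9 of 12 tested members above 0 and a median log2 fold change of 0.34. Adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.000163, and adjusted p = 0.218 with an estimated correlation). The genes that rose included the granzyme genes Gzmk (1.75), Gzma (1.29) and Gzmb (1.32), and Ccl5 (1.04), which cytotoxic CD4+ T cells can also express. The gene that fell was Prf1, which encodes perforin (-0.64). With the block 5 rose and 2 fell adjusted over the list alone, and 1, Ccl5, passed over all genes. The 5 CD8 T cell genes had a median of 0.17 and passed camera with the block (adjusted p = 0.0332) but not without it (0.0702), with an adjusted p of 0.454 and 0.317 at an estimated correlation. Members rising adjusted over the list alone were 2 and 1. Without the block camera called the CD8 list higher without control replicate 2 (0.0306, median 0.59) and without Ogt-KD replicate 2 (0.00305, median -0.14), and the median was -0.13 without control replicate 3 and 0.45 without Ogt-KD replicate 3. B cell markers had 0.16 over 19 genes (camera adjusted p = 0.0659), plasma cell markers -0.13 over 12 (0.660) and stromal and endothelial markers 0.53 over 5 (0.222). Platelet markers had a median of 0.01 over 4 genes with a camera direction of down (0.660). Camera called the B cell list higher without control replicate 2 (0.000370, median 0.42), without Ogt-KD replicate 2 (0.0269) and without Ogt-KD replicate 3 (0.0108), and with single libraries left out its median ran from 0.06 to 0.42. It called the plasma cell list lower without control replicate 1 (1.03e-08) and the platelet list lower without Ogt-KD replicate 3 (0.0151). The stromal median was -0.09 without Ogt-KD replicate 2. The basophil and mast cell list had 2 tested members and the sex-linked list too few, so neither was tested.

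Of the 35 lists tested, camera called 14, of which 10 were higher and 4 lower, and 16 with the block. With an estimated correlation camera called 0 lists in either fit. The fry test called 0 lists without the block, and with it 2, the immediate early and the erythroid list (fry adjusted p = 0.0177 for both). The mixed fry test called 10 without the block and 12 with it.

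**Figure D2:**
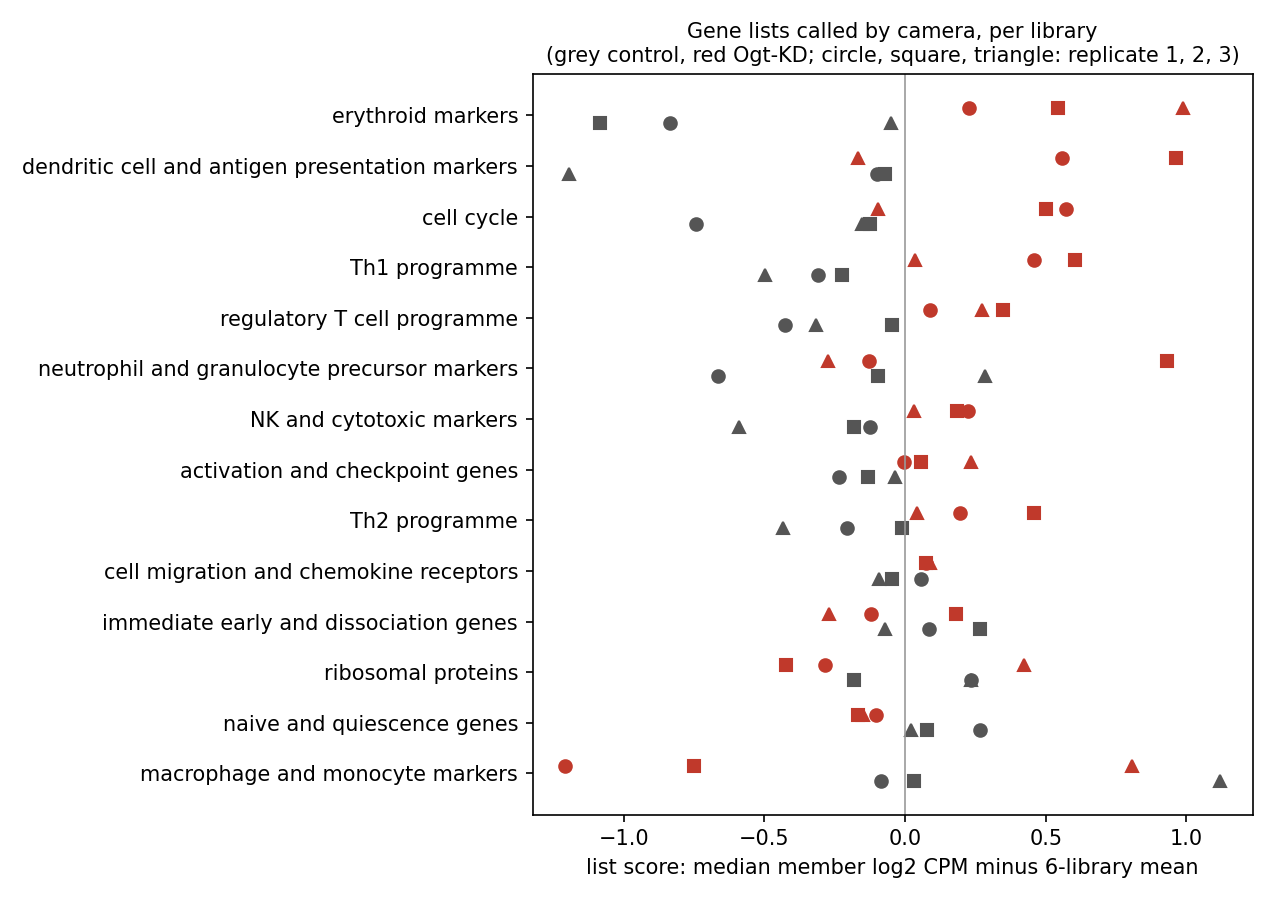
Score of each of the 14 lists called by camera in each of the 6 libraries, as the median over members of log2 CPM minus the mean of the 6 libraries (horizontal axis, log2), with control in grey, Ogt-KD in red, and circle, square and triangle for replicates 1, 2 and 3. The list medians of the log2 fold change run from 1.45 for erythroid genes to -0.48 for macrophage genes, and the replicate 3 libraries of both groups lie above the others in the macrophage list.

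Immunoglobulin segments summed to 2920 ± 1570 CPM in control and 2596 ± 624 CPM in Ogt-KD libraries, a ratio of 0.889 (two-sided exact permutation p = 0.8). T cell receptor segments summed to 2494 ± 241 and 2288 ± 207 CPM, a ratio of 0.917 (two-sided exact permutation p = 0.3). With 3 libraries against 3 the smallest p this test can give is 0.1. In pairs of equal replicate number the T cell receptor sum was lower in the Ogt-KD library in 3 of 3 pairs (2685 and 2278, 2224 and 2085, 2575 and 2499 CPM) and the immunoglobulin sum in 2 of 3. The two-sided exact p over sign flips of the pairs was 0.25 for the T cell receptor sum and 1 for the immunoglobulin sum, and 0.25 is the smallest that 3 pairs can give. The immunoglobulin ratio was 1.10 without control replicate 2 and 0.680 without control replicate 1.

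Genes near Ogt were compared because a floxed allele can carry linked variants of the strain it was made in. The 59 tested genes within 5 Mb of Ogt had a median log2 fold change of 0.04, at percentile 91.15 of 10000 random lists matched on expression. These random lists leave the pairing by replicate number out. In pairs of equal number the median difference in log2 CPM was 0.035, 0.049 and 0.063 in replicates 1, 2 and 3. With the block the median log2 fold change was 0.013. In edgeR 0 of them passed without and with the block, 6 and 8 had an unadjusted p under 0.05, and DESeq2 called 1. The 467 tested X-linked genes had a median of -0.01.

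The authors' own table gives an adjusted p for 26365 genes, of which 110 were under 0.05, with 82 higher and 28 lower in Ogt-KD. Across genes its log2 fold changes and those of edgeR had a Spearman correlation of 0.9999. Of the 110 genes, 20 were among the 47 called by edgeR with the block and 1 was called by edgeR without it. DESeq2 without a block, run here on the same counts, called 111, with 83 higher and 28 lower. These numbers are close to the authors', though the authors' test is not given. In 1 simulation 30.1% of the calls of DESeq2 were false.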

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

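The tests with both replicate 3 libraries left out, DESeq2 with the block, the block without a pair, the GC content and length correction, the list settings of non-robust dispersion and of left-out immunoglobulin, haemoglobin and mitochondrial genes, and all settings for the genes near Ogt, the segment sums and the authors' table were chosen after the data were seen. RLE size factors, total counts only, upper quartile scaling, a mean CPM of at least 5, limma-voom, non-robust dispersion, left-out immunoglobulin, haemoglobin and mitochondrial genes and all 3 FPKM settings gave 1 gene, as did a log2 fold change of at least 1. Total counts only moved the median of all genes by 0.0581. The number of changed genes was 111 with DESeq2, 4 with no filter, 47 with the replicate block, 443 with DESeq2 and the block, 35 without both replicate 3 libraries, and with the block 295, 2 and 295 without replicate 1, 2 and 3 of both groups. Single libraries left out gave 1 to 2. The number of lists called lay between 13 and 21 in every setting, with 16 after the GC content and length correction. Besides the named genes given above, the block changed the calls of the CD8 and mitochondrially encoded lists and no other list call; of 79 named genes, 28 passed with it and not in edgeR without a block, where DESeq2 without a block added 37. The lists called in all 18 edgeR settings were 8, namely Th1, regulatory T cell, naive, activation, cell cycle, dendritic cell, NK and erythroid. The cause of the changes in value was not tested, except that leaving out libraries leaves fewer samples.

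The values below are those whose direction in the test turned and the main counts, sums and medians that moved; for a list the direction is that of camera, which can differ from the sign of its median. List calls that changed with 1 library left out stand with each list above. A mean CPM of at least 5 also called the B cell and CD8 lists (camera adjusted p = 0.0243 and 0.00103), total counts only and no filter the mitochondrially encoded list (0.0339 and 0.0354), and the GC content and length correction with the block the JAK STAT list (0.0248), while the CD8 list, called with the block, was lost under it (0.0530). Ogt had 0.0062 with total counts only, 0.037 without both replicate 3 libraries, 0.035 with the block without replicate 3, and -0.17 to 0.077 with single libraries left out. Bcl6 had 0.032 with total counts only, 0.099 without both replicate 3 libraries, 0.10 with the block without replicate 3, and -0.095 to 0.078 with single libraries left out. Il4 had -0.14 with the block without replicate 1 and -0.15 to 0.39 with single libraries left out. Il17a had 0.63 with the block without replicate 2 and -1.72 to 0.63 with single libraries left out, and Msr1 -2.51 to 0.17. Cd4 had -0.0098 with the block without replicate 1 and -0.046 to 0.11 with single libraries left out. The genes near Ogt had a median of 0.10 with total counts only, 0.061 with no filter, 0.072 with DESeq2, 0.020 with limma-voom, 0.013 with the block, 0.069 with DESeq2 and the block, and 0.020 without both replicate 3 libraries. They had -0.0053 with log2(FPKM+1), -0.0071 with log2(FPKM+0.1), 0.017 with log2(FPKM+1) and no filter, 0.081 and 0.012 with the block without replicate 1 and 2, and -0.013 to 0.084 with single libraries left out. The immunoglobulin ratio was 1.02 without replicate 3 and 1.22 without replicate 2 of both groups, a ratio of mean sums that no block enters, and 0.680 to 1.10 with single libraries left out. A log2 fold change of at least 1 left 57 genes of the authors' table.

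Of lists that camera did not call with all 6 libraries and no block, hexosamine genes had a median of -0.052 with no filter, -0.028 with the block without replicate 2 and -0.029 to 0.11 with single libraries left out. Platelet genes had 0.56 with no filter, 0.021 with the block without replicate 1 and -0.93 to 0.31. Plasma cell genes had -0.0091 with the block, -0.030 without both replicate 3 libraries, -0.76, 0.53 and 0.15 with the block without replicate 1, 2 and 3, and -0.48 to 0.19. Th17 genes had -0.022 without both replicate 3 libraries, 0.049 and -0.024 with the block without replicate 1 and 3, and -0.0058 to 0.20. Interferon genes had 0.061 without both replicate 3 libraries, 0.054 with the block without replicate 3 and -0.43 to 0.40. Cholesterol genes had 0.00039 and -0.0018 in the same order and -0.13 to 0.0083. Follicular helper genes had -0.049 and oxidative phosphorylation 0.081 with the block without replicate 1, with -0.084 to 0.25 and -0.14 to 0.060 for single libraries left out, and NF-kB genes -0.041 to 0.083. Leaving out a pair with the block changed list calls in both directions. Without replicate 1 camera called plasma cell genes lower (adjusted p = 9.93e-26), oxidative phosphorylation higher (0.0408), cholesterol (0.00341) and interferon genes (0.00718) lower and CD8 genes higher (0.0281), and lost ribosomal (0.388) and neutrophil genes (0.0689). Without replicate 2 it called plasma cell (0.00635), Th17 (0.00878), follicular helper (0.0135), B cell (0.000108) and CD8 genes (0.00157) higher and interferon (0.000197), cholesterol (0.0218) and mitochondrially encoded genes (0.0234) lower, and lost neutrophil genes (0.979). Without replicate 3 it called B cell genes higher (0.0484) and mitochondrially encoded (4.57e-05) and platelet genes (0.0484) lower, and lost migration genes (0.116). Leaving out both replicate 3 libraries without a block also called mitochondrially encoded (0.000328) and platelet genes (0.0352) lower. In data simulated from these 6 libraries edgeR without a block recovered 8.4% of genes changed 1.5-fold, 44% at 2-fold and 96.4% at 8-fold; other depths and numbers of libraries were not simulated.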

Other observations

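The tests of heat shock, pancreatic and dendritic cell gene lists, of activated against naive cells, and all tests on Gm33707 and on dendritic cell against macrophage genes were chosen only after the result was seen; the test of GC content and length was added after the data were seen, though before its own value was, and the counts of splits were not. Heat shock chaperone genes, which help proteins fold under stress, were lower in Ogt-KD libraries: 25 of 25 tested genes lay below 0, the median log2 fold change was -0.48, and 12 fell adjusted over the list alone (camera adjusted p = 4.79e-20 over 4 lists, adjusted p = 0.0807 with an estimated correlation). Hsph1, a co-chaperone of Hsp70, stood at 193 ± 62.5 CPM in control and 84.9 ± 30.5 CPM in Ogt-KD libraries (log2 fold change -1.19, SE 0.34, edgeR adjusted p = 0.556, 0.0143 with the block). Fkbp4 (-0.67) and Dnajb4 (-0.76) belong to the list. With the block 18 fell adjusted over the list alone and 2, Hsph1 and Fkbp4, over all genes (adjusted p = 0.0528 with an estimated correlation). The list was written after Hsph1, Fkbp4 and Dnajb4 were seen to be low, so its direction is not independent evidence.

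Transcripts of pancreatic digestive enzymes, which CD4+ T cells do not make, were counted in every library. They summed to 17.5, 122 and 88.3 CPM in control and 14.4, 22.2 and 40.2 CPM in Ogt-KD replicates 1, 2 and 3 (two-sided exact permutation p = 0.3, n = 3 each, and 0.25 over sign flips of the 3 pairs, the smallest possible), so that control replicate 1 lay within the Ogt-KD range. Try4 and Ctrb1 had log2 fold changes of -3.40 and -3.42 (edgeR adjusted p = 0.624 and 0.667, 0.0363 for both with the block). The pancreatic list, with 11 tested genes, had a median of -3.28 (camera adjusted p = 2.72e-06, adjusted p = 0.156 with an estimated correlation). With the block 8 of its genes fell adjusted over the list alone and 6 over all genes, against 0 and 0 without it. Without control replicate 2 the median was -2.15 (camera adjusted p = 0.0140), and with the block without replicate 2 of both groups it was -1.73. Msr1, a macrophage scavenger receptor (-1.14), the eosinophil chemokine receptor gene Ccr3 (-1.16) and the semaphorin receptor gene Plxnb2 (-0.72) were also lower with the block (edgeR adjusted p = 0.0443, 0.0363 and 0.0363). Without control replicate 3 and without a block Msr1 had 0.17, Ccr3 -0.40 and Plxnb2 -0.20, and without Ogt-KD replicate 3 they had -2.5, -2.2 and -1.3.

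The pair Gm33707 and Gm38326 on chromosome 3 had reads in all 3 Ogt-KD libraries and 1 read each over the controls. The tables argue against reads shared with a gene that both groups express. The Gm33707 transcript is 89.2% identical to Eno1 over 576 aligned bases, and Eno1 stood at 554 and 513 CPM in control and Ogt-KD libraries. Yet Gm33707 stood at 0.0188 and 41.0 CPM. The larger of the 2 control levels, that of Gm38326, was 0.96% of its Ogt-KD level. For a single mislabelled library or a swap of 1 library per group, 0 libraries had the other group's level of Gm33707. That count cannot decide the question, because the gene was picked for its separation under the given labels. An exchange of all labels between the groups would also give 0 and cannot be told apart from a rise in the Ogt-KD libraries, because Ogt lay below each control library in 1 Ogt-KD library only. A change of the locus carried by the Ogt-KD mice, such as a transgene inserted there or a linked strain variant, is a candidate explanation that cannot be told apart from an effect of the genotype, because all 3 Ogt-KD libraries share both. The median log2 fold change of the 8 other tested genes within 1 Mb was 0.31 (range -0.21 to 1.16), and none passed in edgeR, while 3 of them were higher and 0 lower at an unadjusted p under 0.05. The untested pseudogene Tgif1-ps, also within 1 Mb, had 5, 15 and 3 reads in the Ogt-KD libraries against 0, 0 and 0.

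The Th1, regulatory T cell and cell cycle lists were higher and the naive list lower in Ogt-KD libraries. The data argue against GC content or gene length as the whole cause. Both together explained a share of 0.00411 of the variance of the fold changes with the block, weighted by their SE, with values for 99.9% of the genes. After correction each list kept at least 0.959 of its median with the block. A larger share of activated and a smaller share of naive cells among the isolated cells may account for the lists. The naive median was -0.25 without the block, but bulk RNA holds no count of cells. Such a shift in shares thus cannot be told apart from a change within cells.

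Without the block, the number of lists called was no larger than other groupings of the 6 libraries gave. Of 10 splits, the real one included, 6 gave at least the real 14, and the highest other gave 17. That number is thus no evidence of a difference between the groups. With the block, of the 4 splits that part all 3 pairs, 1, the real one, gave at least the real 16, and the highest other gave 13. Splits were too few for a share under 0.05 in either case. For genes, the real split gave 1 in edgeR and 111 in DESeq2, as many in 3 of 10 splits for each, with 785 and 1895 as the highest other; with the block the real split gave 47, 1 of 4 gave as many, and the highest other gave 1. The split with 785 genes set control replicates 1 and 3 and Ogt-KD replicate 3 against the rest, which points to a structure of the samples along the first principal component; it keeps the libraries of replicates 2 and 3 together, while the 4 splits with the block part every pair.

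Dendritic cell and MHC class II genes were higher and macrophage genes lower in Ogt-KD libraries. A lower share of T cells with more of every other type would raise both lists. The dendritic cell score exceeded the macrophage score by 1.64 (SE 0.153, mean of 3 replicate pairs), with the macrophage score at -0.74 (SE 0.235). These values cannot decide the question, because both lists were picked for their opposite directions. The macrophage fall also rests on single libraries, with a median of 0.05 without control replicate 3. More dendritic cell RNA in Ogt-KD libraries stays open and cannot be told apart from a change within the isolated cells, because the genes at hand belong to the list that was seen to be higher, so their direction is not independent evidence. The 9 tested dendritic cell genes outside MHC class II had a median log2 fold change of 1.12 (camera adjusted p = 2.72e-06, adjusted p = 0.156 with an estimated correlation), and the 9 MHC class II genes 0.89 (2.82e-08 and 0.156). The first median was 0.74 without control replicate 3 and the second 0.55 without Ogt-KD replicate 2. With the block 7 genes rose adjusted over the list alone in each of these lists, against 0 and 1 without it, and 2 in each passed over all genes, against 0. The most abundant genes of the dendritic cell list were Cd74, at 377 and 670 CPM, and H2-Ab1, at 203 and 419 CPM, both also made by B cells, while Cd4 stood at 822 and 838 CPM. An isolation by CD4 would not remove the splenic dendritic cells that carry CD4, and a biological difference in the cells present in the spleen stays open and untested.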
